A study of Mus musculus with 2 samples.

How the data were processed

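DNase-seq was performed on ovary tissue of 2 female mice at 36 days of age, from the F1 hybrid of the C57BL/6J and CAST strains that is sold as B6CASTF1/J. DNase I cuts DNA where it is not wrapped in nucleosomes, so a pile of cuts marks open chromatin, and a short protected stretch inside an open site marks a footprint of bound protein. The labels give 1 group, ovary, with biological replicates 1 and 2, and number the females of the 2 replicates differently, with a biosample entry each, so each library was taken as 1 animal. Both carry the same donor entry in the labels, which was read as the strain and not as 1 shared animal.

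Coordinates are on mm10, per the labels, and the reference used here was GRCm38 with GENCODE gene models, which is the same build. Intervals were called separately for each library from that library's own filtered alignments, per the descriptions deposited beside the files. The aligner, the callers, their versions and their thresholds are not given in the sources used here. Each peak carries a signal value that the authors deposited, and its scaling is not given in the sources used here. In each library 100% of these signal values were whole multiples of 1 step, within a tolerance of 0.05 of a step, as a read count scaled by 1 factor would be, but that 1 step is 1 read was not shown. If the values are CPM, the steps correspond to 153540906 reads in replicate 1 and 152812217 in replicate 2. The authors deposited false discovery rates per base as q-values, listed only up to 0.0499 in both libraries. Footprints carry a deposited score that is 0.01 in every line, whose meaning is not given in the sources used here, so only their positions were used.

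The authors deposited a longer and a shorter list of peaks for each library. Every peak of the longer lists contained a base with a listed q-value, and 100% of the shorter lists' peaks reached a q-value of 0.001. The longer list was used for the main results. That choice was made after the lists had been seen and before any result was computed.

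Peaks of the 2 libraries that overlapped by at least 1 base were called shared, and one-to-one pairs were those with the longest overlap in both directions. Overlaps were counted in Python 3.11.15 with numpy 2.4.6, and bedtools 2.31.1 gave equal counts of 82466 and 81895. The overlap expected by position alone was the mean of 100 shuffles within chromosomes. The plan had named bedtools for this count. A promoter counted as open when a peak lay within 500 bp of an annotated transcription start site of a protein-coding gene in both libraries. Distal peaks were shared peaks whose centre lay over 1000 bp from every annotated start site, and each was assigned to the protein-coding gene with the nearest one. For the place of peaks in the annotation, a promoter reached 1000 bp to either side.

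A set of 23 gene lists and 27 consensus motifs, with the tests and most alternatives, was fixed before the data were examined. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests (scipy 1.17.1), adjusted by Benjamini-Hochberg over the 23 lists. Distal peak counts and library ratios were given as percentiles among 10000 random lists of equal size, matched on the length of a gene's territory or on mean peak value, and lists outside the range from 2.5 to 97.5 were called. Motif matches within 75 bp of distal peak centres were compared with windows 2000 bp to each side that touched no peak, and footprints at motifs with footprints at the reversed, not complemented, consensus, both by two-sided Fisher's exact tests. Genes and peaks, not animals, are the units of these tests, so they describe these 2 libraries. There was no contrast between groups and no test between the animals. The comparison of motifs at peaks in favour of each library, in the closing section, also has peaks as its units. Values are given as mean ± SD of the 2 libraries. Intervals on a single gene's ratio are 95% intervals for counting error only, and take 1 step as 1 read.

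The genes named were set by rule before the data were examined. From each ovarian list came up to 4 genes, and from each other list up to 2, with the highest mean promoter value, with up to 2 genes per list, in alphabetical order, that had no promoter peak in either library. The 5 list genes with the highest and the 5 with the lowest library ratio, the 5 strongest distal and promoter sites, the motifs with the highest and lowest ratios, and NR5A, forkhead, GATA and estrogen receptor were also named. One item that the rule names is not reported here. Genes outside the rule are marked as chosen after their values were seen.

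On simulated data, the overlap count returned the planted share of 59.3% exactly. The list test on 21853 genes was tried on single lists by their unadjusted p. There 78% of lists with 95% of promoters open and 98% of lists with 25% open were called, against 3% of lists with no difference. These shares do not give the power of the reported test, which is adjusted over all lists. Lists given 2 added distal peaks per gene were called in 91% of draws, and a planted library shift of 0.50 on the log2 scale in 96.7%, against 1% and 1.67% without a shift. A motif planted in 5% of 5000 windows was found at 4.86 percentage points with 0 other motifs called. The simulated windows and their controls had equal base composition, unlike the real peaks and flanks. This trial therefore says nothing about calls that arise from base composition.

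Alternatives were other overlap rules, the peaks with values above the median, the shorter peak list, other promoter widths and start sites, a background matched on promoter CpG ratio, other distances and summaries, other control windows, and each library alone. Motif controls of equal GC content, random lists matched on both CpG ratio and value, ratios of single genes relative to promoters of like value, and the removal of the 1000 strongest shared peaks were chosen after seeing the data. Peaks on unplaced contigs and the mitochondrial genome were left out.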

Results

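Open chromatin was mapped by DNase-seq in the ovaries of 2 female mice of 36 days, 1 library per animal. Replicate 1 held 109169 peaks over 22.1 Mb and replicate 2 held 114462 peaks over 25.4 Mb, which is 0.872% ± 0.0855 of the genome (SD, n = 2). The median peak was 185 bp wide with a value of 0.808 in replicate 1, and 200 bp wide with a value of 0.648 in replicate 2. If 1 step of the values is 1 read, a median peak rested on 124 reads in replicate 1 and 99 in replicate 2. The libraries also held 301406 and 294269 footprints, with median widths of 10 and 9 bp. With 1 group of 2 animals, the comparisons are between the animals, between gene groups within the tissue, and between open sites and their flanks.

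The 2 ovaries shared most of their open sites, and the sites of high value were shared most often. Of the peaks of replicate 1, 75.5% overlapped a peak of replicate 2, and 71.5% of the peaks of replicate 2 overlapped one of replicate 1, against 1.92% and 1.75% after shuffling. Peaks found in one library alone were weak, with median values of 0.404 and 0.373, against 1.08 and 0.877 for shared peaks. Across 79447 one-to-one pairs the values correlated with Pearson's r = 0.953 on the log10 scale and Spearman's rho = 0.932, a correlation across peaks, which are not independent replicates. Values of replicate 2 were lower, with a median log2 ratio of -0.41 and an SD of 0.49 across peaks. This ratio went from -0.11 in the weakest 10% of the shared peaks to -0.98 in the strongest 10%. It also went with base composition, from a median of -0.02 in the 20% of peaks with the lowest GC content to -0.89 in the 20% with the highest.

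**Figure D1:**
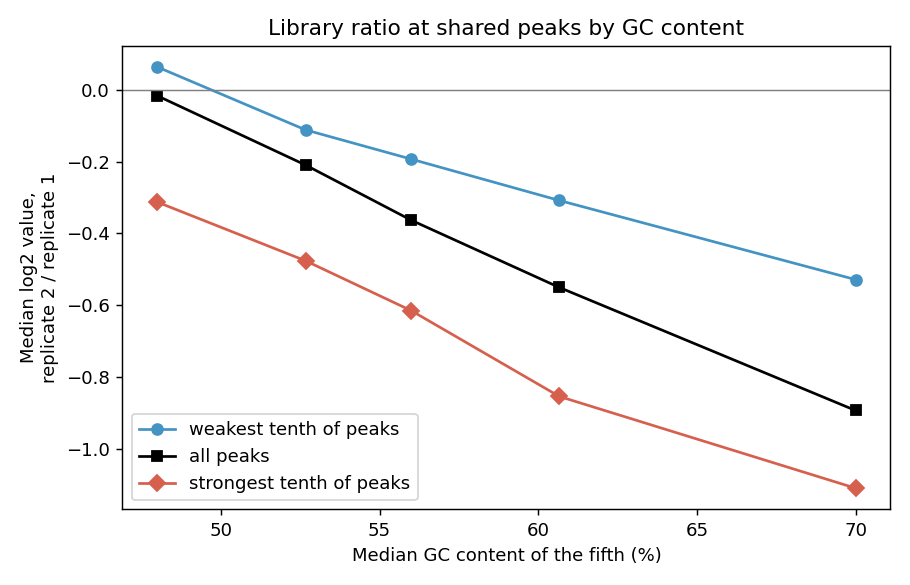
Median log2 ratio of peak values, replicate 2 over replicate 1, on the y axis, for 5 equal classes of the 79447 shared peaks by GC content, with the median GC content (%) of each class on the x axis. Lines join the weakest 10%, all peaks and the strongest 10% within each class, and the line for all peaks runs from -0.02 to -0.89.

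The strongest promoter site lay on chromosome 17 from 39846781 to 39846900, in an exon of a noncoding gene, with a value of 84.6 ± 5.37 (SD, n = 2). It was followed by sites 8 bp from the start of Hjurp, a chaperone of centromeric histone, on chromosome 1 (88277521 to 88277760, 41.1 ± 17.9), and 11 bp from the start of Dynlt1b, a dynein light chain, on chromosome 17 (6430021 to 6430180, 37.8 ± 18.1). The next were in an intron of Zc3h7a on chromosome 16 (11144171 to 11144320, 35.5 ± 5.29) and in an exon of Kpna1, an importin, on the same chromosome (35981661 to 35981840, 34.2 ± 10.9). The strongest distal site lay in an exon of Lars2 on chromosome 9 (123461901 to 123462100), at 49.0 ± 5.73. The other distal sites of this rank were intergenic on chromosome 3 (5860361 to 5860530, 40.2 ± 6.37), in an intron of Il31ra on chromosome 13 (112578161 to 112578320, 40.1 ± 2.43), 21.6 kb from Igf2bp3 on chromosome 6 (49236421 to 49236620, 39.9 ± 3.13) and in an exon of Cers5 on chromosome 15 (99735661 to 99735920, 34.5 ± 3.04). Whether these sites lie in sequence with extra copies in the genome was not analysed here.

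Promoters made up 32.0% ± 0.961 of the peaks (SD, n = 2), against 5.88% of genome positions. Introns held 32.9% ± 0.942 of the peaks, intergenic sequence 29.8% ± 0.592 and exons 5.33% ± 0.574, against 37.3%, 53.7% and 3.09% of positions. The share in promoters was 24.7% when a promoter reached 500 bp, and 45.1% among the peaks with values above the median. Chromosome X held 17.8 peaks per Mb in both libraries, against 43.1 and 45.2 on the autosomes.

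Granulosa cell genes and regulators of gonad development were open at their promoters, while oocyte and lymphocyte genes were mostly not called open. The libraries are of whole ovary tissue, so a promoter open in only a small part of the cells may give no peak. A missing promoter peak was therefore not read as a promoter closed in every cell type. Of 20 granulosa genes, 19 had a promoter peak in both libraries, against 65.6% of other protein-coding genes (adjusted p = 0.00955, Fisher's exact test over 23 lists). The highest values were at Foxl2, the transcription factor of granulosa identity, on chromosome 9 (98955288 to 98958543), at 4.66 ± 2.09 (SD, n = 2), Nppc, the precursor of C-type natriuretic peptide, at 4.64 ± 1.95, Inhba, the activin beta A subunit, at 4.53 ± 1.34, and Kitl, the ligand of the Kit receptor, at 4.32 ± 1.78. Cyp19a1, which makes estrogen, was the exception and had no promoter peak in either library, although 3 distal shared peaks were nearest to it. All 23 gonadal regulators were open (adjusted p = 6.704e-04, Fisher's exact test), led by Cited2 (14.2 ± 5.95), Foxo1 (6.97 ± 4.27), Nr3c1, the glucocorticoid receptor (6.97 ± 2.63), and Emx2 (5.94 ± 2.46). With the most upstream start site alone this call was lost (adjusted p = 0.254, Fisher's exact test). Over the genome, 14332 of 21853 protein-coding genes had a promoter peak in both libraries and 771 in one alone.

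Theca, steroidogenic and luteal genes were open in most cases but did not pass the test, while cholesterol synthesis genes did. Of 16 theca and steroidogenic genes, 14 were open (adjusted p = 0.115, Fisher's exact test), led by Por (13.9 ± 6.79) and Fdxr (12.0 ± 6.05), which pass electrons to steroid-making enzymes, Scarb1, the receptor that takes up high-density lipoprotein cholesterol (7.04 ± 4.00), and Fdx1 (6.40 ± 3.40). Hsd3b1 had no promoter peak. Of 12 luteal genes, 10 were open (adjusted p = 0.344, Fisher's exact test), with Vegfa at 6.07 ± 1.66, Parm1 at 5.93 ± 2.97 and Star, which brings cholesterol into mitochondria, at 2.97 ± 1.18. Akr1c18, which breaks down progesterone, had no promoter peak. All 16 cholesterol synthesis genes were open (adjusted p = 0.0065, Fisher's exact test), with Dhcr7 at 15.2 ± 9.56, whose start lies within 1 kb of that of Nadsyn1, and Insig1 at 13.6 ± 8.88. Of 15 genes of the response to luteinising hormone, 14 were open (adjusted p = 0.0473, Fisher's exact test), led by Rgs2 (11.4 ± 5.78), Ctsl (8.32 ± 3.81), Cebpb (6.85 ± 3.0) and Edn2 (5.83 ± 3.10). This last call was lost without replicate 1 (adjusted p = 0.054, Fisher's exact test), with the most upstream start site alone (adjusted p = 0.127) and among peaks above the median value (adjusted p = 0.251).

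Oocyte genes were open in 6 of 22 cases (adjusted p = 0.0017, Fisher's exact test). The open ones were led by Dazl (6.99 ± 4.14), Kpna7 (6.78 ± 4.67), which shares its start region with Arpc1a, Kit (3.66 ± 2.14) and Lhx8 (0.976 ± 0.0567). Bmp15, an oocyte growth factor, and Ddx4, a germ cell helicase, had no promoter peak. None of 12 lymphocyte genes was open (adjusted p = 6.315e-05, Fisher's exact test), Cd2 among them. Of 14 macrophage and myeloid genes 2 were open (adjusted p = 6.704e-04, Fisher's exact test), Cd14 (1.11 ± 0.0609) and Cd68 (0.761 ± 0.0256), while Adgre1 and C1qa had no promoter peak.

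Among lists of other tissues, 2 of 14 hepatocyte genes (adjusted p = 6.704e-04), 2 of 12 spermatogenic genes (adjusted p = 0.00278) and 5 of 14 skeletal muscle genes (adjusted p = 0.0468) were open by Fisher's exact test. The hepatocyte genes were Ahsg (0.470 ± 0.0446) and Cyp2e1 (0.457 ± 0.103), with no promoter peak at Alb or Apoa1. Tssk6 at 10.4 ± 3.27, which shares its start region with Ndufa13 and Yjefn3, and Zpbp at 4.53 ± 1.62 were the spermatogenic ones, and Acr and Acrv1 had none. Mylpf (8.30 ± 6.11), whose start region is shared with Tbc1d10b, and Pygm (1.89 ± 1.08) led skeletal muscle, where Myf6 and Myh1 had none. The skeletal muscle call was lost without replicate 1 (adjusted p = 0.149, Fisher's exact test) and without replicate 2 (adjusted p = 0.132), and also with the most upstream start site alone (adjusted p = 0.127) and with promoters of 1 kb to either side (adjusted p = 0.363). Of 14 neuronal genes 7 were open (adjusted p = 0.355, Fisher's exact test), with Syp at 3.26 ± 1.52 and Syn1 at 3.14 ± 1.81, and none at Neurod2 or Neurod6. All 16 housekeeping genes (adjusted p = 0.0065), 12 mitosis genes (adjusted p = 0.0235) and 12 immediate early genes (adjusted p = 0.0235) were open by Fisher's exact test. They were led by Rplp0 (16.7 ± 6.49) and Actb (15.7 ± 8.57), Ccna2 (11.9 ± 6.35) and Cdk1 (9.97 ± 3.85), and Egr1 (11.7 ± 6.5) and Jun (11.6 ± 4.09). The immediate early call was lost with the most upstream start site alone (adjusted p = 0.502, Fisher's exact test).

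Support cell lists did not pass the test against all other genes. Open promoters numbered 11 of 14 in stroma, with Pdgfra at 5.50 ± 2.52, Fbln1 at 4.08 ± 1.76 and none at Mfap5, and 10 of 12 in smooth muscle and pericytes, with Mcam at 3.05 ± 1.19, Myh11 at 2.83 ± 1.23 and none at Actg2. Endothelial genes were open in 8 of 14 cases, with Egfl7 at 2.39 ± 0.791 and Sox18 at 2.28 ± 0.722, and no promoter peak at Erg or Pecam1. Surface epithelium had 8 of 12, with Wt1 at 4.43 ± 2.61 and Cdh1 at 2.16 ± 0.778, and none at Lrrn4 or Msln. Adipocyte genes had 7 of 11, with Pnpla2 at 8.95 ± 5.10 and Lipe at 4.27 ± 2.5, and none at Adipoq or Cfd. Sertoli cell genes had 8 of 10, with Sox8 at 4.22 ± 1.64 and Sox9 at 2.88 ± 0.747, and none at Rhox5 or Tsx. Oviduct epithelium had 7 of 10, with the ciliary genes Rsph1 at 18.6 ± 6.14 and Foxj1 at 9.49 ± 3.34, and none at Sntn.

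CpG-rich promoters are open in many tissues, and against random lists matched on promoter CpG ratio the calls differed. Granulosa (percentile 99.8), theca (97.9), stroma (99.9) and smooth muscle (99.2) lay above the range of random lists. Oocyte (0.10), lymphocyte (1.36) and neuron (0.775) lay below it. The gonadal regulators (97.7) also passed the upper limit, but all 23 were open, so a random list could equal but not exceed them. Their percentile is the highest this measure allows that list, and random lists had a median of 91.3% open. These percentiles are not adjusted for the 23 lists. The calls ended for response to luteinising hormone (91.2), macrophage (23.5), hepatocyte (17.0), spermatogenic (3.35) and skeletal muscle (28.2). The housekeeping (80.8), cholesterol synthesis (79.7), mitosis (68.8) and immediate early (70.1) lists were fully open and stood at the highest percentile that this saturated measure allows them, so it says nothing about their calls.

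**Figure D2:**
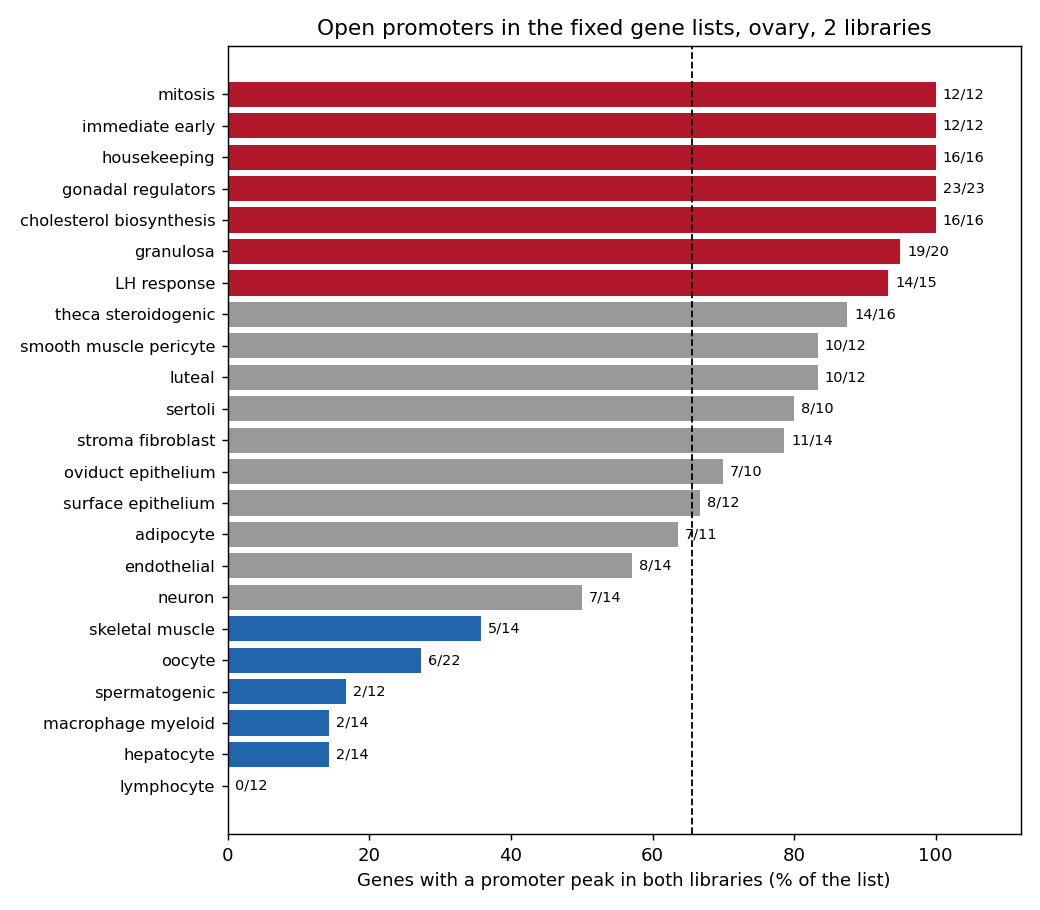
Share of each fixed gene list with a promoter peak in both libraries (x axis, % of the list; y axis, list), with counts beside the bars. The dashed line marks the 65.6% of all protein-coding genes, red and blue bars passed an adjusted p of 0.05 above and below it, and the granulosa list stands at 19 of 20.

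Gonadal regulator, luteal, granulosa and theca genes also had more distal open sites around them than random lists, while genes of the response to luteinising hormone (median 4 against 3, percentile 71.8), stroma (96.6) and surface epithelium (77.8) lay inside the random range. Gonadal regulators had a median of 9 shared distal peaks per gene, against 3 in random lists matched on territory (percentile 99.99). Luteal genes had 7.5 against 2.5 (99.9), granulosa genes 5 against 2 (99.5) and theca genes 3 against 1 (99.1). These lists share genes, so their percentiles are not independent. Star, Scarb1, Cyp11a1, Lhcgr and Hsd3b1 are in both the luteal and theca lists. Foxl2, Nr5a2 and Esr2 are in both the granulosa and gonadal regulator lists, and Nr5a1 is in both the theca and gonadal regulator lists. Immediate early genes had 6.5 against 1.5 (99.995), endothelial genes 5 against 2.25 (98.2), oviduct genes 4 against 1 (99.9) and housekeeping genes 2 against 0.5 (99.7). The oocyte median of 1 equalled that of random lists (51.7). With 51532 shared distal peaks in all, no list lay below the random range. With distal peaks limited to over 2 kb and at most 100 kb from a start site, the granulosa (80.6), luteal (95.2) and housekeeping (92.1) lists lay inside the range and smooth muscle (99.0) above it, and among peaks above the median value the luteal (83.9), endothelial (89.1), oviduct (96.1) and housekeeping (97.0) lists did. By mean count the oviduct (84.1) and endothelial (89.9) lists lay inside it and stroma (98.2) and smooth muscle (99.2) above, without replicate 1 the endothelial list lay inside (96.9), and without replicate 2 surface epithelium (99.6) and stroma (98.5) lay above.

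The distal peak of highest value near Foxl2 lay 9.98 kb from its start on chromosome 9 (98965161 to 98965380) at 5.11 ± 1.95 (SD, n = 2), outside the gene, and was picked after its value was seen. Near Cyp19a1, the 3 distal peaks were at 54163246 to 54163378, outside the gene, and at 54204265 to 54204321 and 54204581 to 54204860 inside it, all on chromosome 9. Their values were 0.536 ± 0.150, 0.561 ± 0.118 and 0.849 ± 0.0398.

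Few gene lists set the promoters of the animals apart once the general shift was removed. The median promoter ratio of replicate 2 over replicate 1 was -0.89 on the log2 scale over 14332 genes, and ratios are given relative to it. Of 19 lists with at least 3 open genes, 1 lay outside the random range, skeletal muscle at -0.24 against 0.28 in random lists (percentile 0.58), on 5 genes. The range holds 95% of random lists and is not adjusted for the 19 lists, so 1 list can fall outside it without any difference. Ratios of single genes had an SD of 0.39 over the 14332 genes, and the genes named next were picked as extremes. Across shared peaks, 49.0% lay over 2 counting SDs from the median ratio, so counting intervals understate the spread between libraries. The lowest ratios of single list genes were at Mylpf (-0.78, 95% counting interval -0.91 to -0.64), Kpna7 (-0.65), Hprt (-0.62), Cbx2 (-0.56) and Insig1 (-0.55). The highest were at Dcn (1.88, 1.37 to 2.41), which encodes the stromal proteoglycan decorin, Cyp2e1 (1.35), Tnfaip6 (1.32), Acta1 (1.21) and Zar1 (1.09), genes of low value. These sizes depend on the centre: relative to distal peaks, at -0.29, all 10 were lower by 0.60, with Mylpf at -1.37, Insig1 at -1.15, Dcn at 1.28 and Zar1 at 0.50. Relative to promoters in the same 10% class of value they were -0.71, -0.37, 1.43 and 0.64, and none of the 10 changed sign under either centre. At distal peaks the skeletal muscle difference was turned to 0.12 above random lists, and with 1 library per animal no test between animals is possible.

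Distal open sites carried matches to the motifs of CTCF and of the nuclear receptor NR5A, the family of Nr5a1 and Nr5a2 that drives steroid genes. A match to a consensus does not show which protein bound the site. CTCF, which anchors chromatin loops, matched 8.28% of 51531 distal windows against 0.0403% of 96804 flanking windows, a ratio of 206. NR5A matched 4.88% against 1.83%, a ratio of 2.67 (adjusted p = 6.334e-229, Fisher's exact test over 27 motifs). The neuronal repressor motif REST was found in 217 peaks and 2 flanking windows. NFI reached a ratio of 24.2, NRF1 14.8 and estrogen receptor 14.1, the last with 75 matches in peaks. In all, 18 motifs were more frequent in peaks and 5 less frequent. Without replicate 1 the call on MEF2, one of the less frequent, was lost (adjusted p = 0.724, Fisher's exact test) while STAT and HNF4 passed as more frequent, and without replicate 2 RUNX passed as less frequent (ratio 0.902).

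Forkhead, the motif of Foxl2 and its relatives, and GATA, bound by Gata4 and Gata6, were among the less frequent motifs, with ratios of 0.719 (adjusted p = 2.733e-41, Fisher's exact test) and 0.775 (adjusted p = 7.655e-40). The lowest ratios were at LHX homeobox (0.367), SOX (0.578) and forkhead. Peaks held 54.2% GC against 45.3% in flanks, and in 38099 pairs of windows of equal GC content forkhead reached 1.60 and GATA 1.52, both more frequent in peaks. There 21 motifs were more frequent and 0 less frequent, SOX was at 1.27, NR5A at 2.39, and LHX homeobox at 0.969 no longer passed (adjusted p = 0.849, Fisher's exact test).

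**Figure D3:**
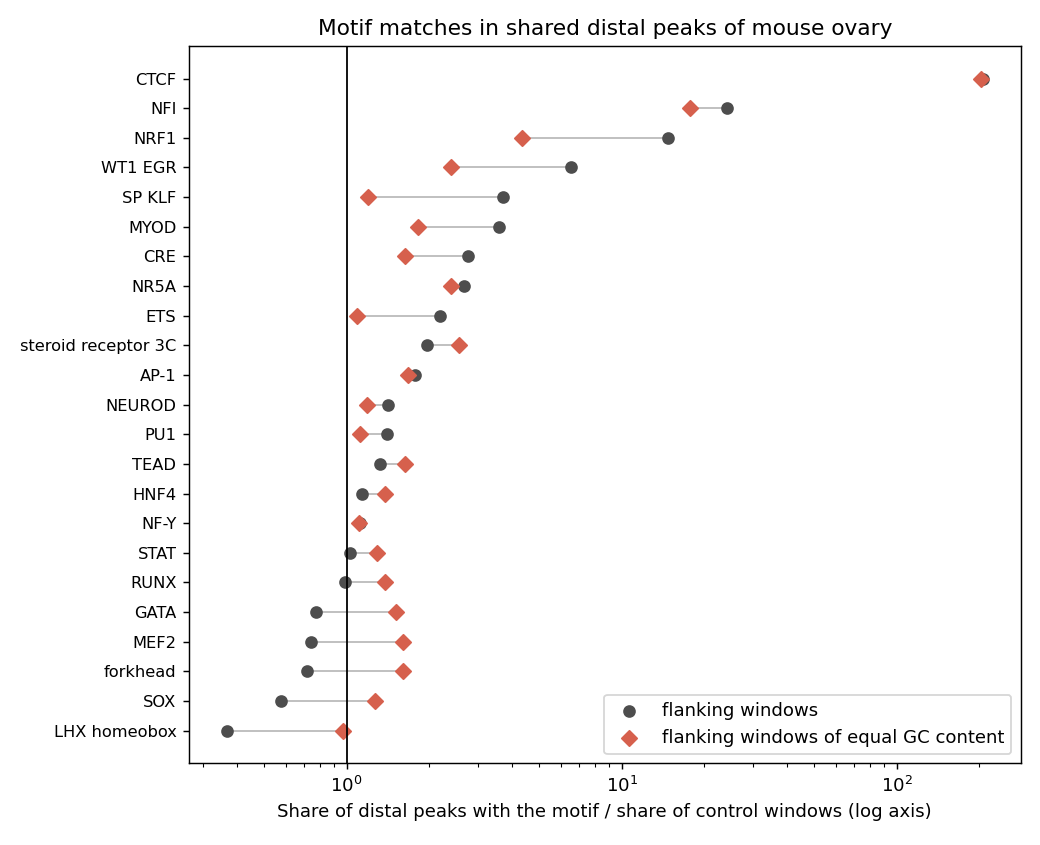
Ratio of the share of shared distal peaks with a motif to the share of control windows (x axis, log scale; y axis, motif), with flanking windows as circles and windows of equal GC content as diamonds. Motifs with 3 or fewer matches in control windows are left out, and forkhead moves from 0.719 to 1.60.

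Matches of 7 motifs held more footprints than their reversed consensus, those of NEUROD, CRE, NF-Y, WT1/EGR, ETS, NR5A and estrogen receptor, and matches of forkhead and GATA held fewer. The matches and reversed matches were not made equal in peak value, with which footprints became more common, or in CpG content. These differences alone therefore do not show binding at the motif or its absence. CTCF matches overlapped a footprint in 94.9% of 4290 cases in replicate 1 and 94.8% in replicate 2, but its reversed consensus had only 2 matches to compare with. NR5A matches did so in 50.1% and 41.3% of 2629 cases, against 30.4% and 22.4% at the reversed consensus, and estrogen receptor matches in 76.4% and 74.8% of 123, against 18.8% and 43.8% of only 16 reversed matches. With a footprint required in both libraries, the shares were 28.8% for NR5A against 15.6% (adjusted p = 3.243e-05, Fisher's exact test) and 64.2% for estrogen receptor against 12.5%, or 2 of the 16 (adjusted p = 3.203e-04). NEUROD, a motif of neuronal factors, stood at 28.8% against 10.4% (adjusted p = 2.506e-16, Fisher's exact test), and CRE at 56.3% against 21.2% (adjusted p = 1.225e-12). The NEUROD consensus CAGATGG is also 1 form of a stretch inside the CTCF consensus CCASYAGRKGGC. CTCF matches had footprints in both libraries in 92.1% of cases. Part of the NEUROD footprints can therefore be those of CTCF sites, and how many was not counted. Forkhead matches had footprints in 5.01% of cases, fewer than the 9.16% at the reversed consensus (adjusted p = 4.752e-06, Fisher's exact test), and GATA matches in 4.63% against 7.39% (adjusted p = 1.356e-04). In replicate 1 alone GATA did not pass (adjusted p = 0.456, Fisher's exact test). ETS passed with both libraries but in neither alone, TEAD in each alone but not with both, SOX in replicate 1 alone, and AP-1 and STAT in replicate 2 alone.

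A smaller share of footprints than of peaks overlapped between the libraries. Footprints are far narrower than peaks, so the shares do not compare how well the 2 kinds of interval repeat. Of the footprints, 47.9% in replicate 1 and 50.2% in replicate 2 overlapped one of the other library. Within shared peaks the shares were 56.9% and 62.5%, against 33.7% and 36.2% when footprints were moved at random inside their peak. The share of peaks with a footprint rose with peak value, from 31.5% in the weakest 10% of peaks to 99.99% in the strongest in replicate 1 and from 30.2% to 99.96% in replicate 2. A missing footprint at a weak site was therefore not read as missing protein.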

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

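Equal GC content of the flanks, lists matched on both CpG ratio and value, single-gene ratios relative to promoters of like value, and removal of the 1000 strongest shared peaks were tests chosen after the results were seen. The mean share of peaks in common was 73.5%, and it was 59.6% with 50% reciprocal overlap, 85.8% among peaks above the median value and 78.7% in the shorter list. Pearson's r of 0.953 was 0.956, 0.914 (distal peaks), 0.949 (values above the median) and 0.949 (without the 1000 strongest), all outside its 95% interval, which is narrow because of the number of peaks. Promoters held 24.7% of peaks at 500 bp and 45.1% above the median value. Lists more open went from 7 to 4 with the most upstream start site alone, and lists less open from 6 to 3 against a CpG-matched background. Lists above the random range for distal peaks went from 8 to 4 among peaks above the median value. For library differences, distal peaks gave 0 lists below in place of 1, with skeletal muscle at 0.12, and lists matched on both CpG ratio and value gave 1 list above in place of 0, immediate early genes (percentile 98.1). Motifs less frequent in peaks numbered 5, but 2 against the reversed consensus and 0 with flanks of equal GC content, against 18, 22 and 21 more frequent. Against the reversed consensus forkhead turned to 1.29, GATA to 1.84, SOX to 1.36, LHX homeobox to 1.09 and MEF2 to 3.22, and CRE turned to 0.467 and ETS to 0.228. The CRE and ETS motifs hold a CpG and their reversed forms hold none. This control therefore does not keep CpG content equal and cannot decide on these motifs. With flanks of equal GC content CRE stood at 1.63, and ETS, at 1.09, did not pass. With flanks of equal GC content forkhead turned to 1.60, GATA to 1.52, SOX to 1.27 and MEF2 to 1.61. Motifs with fewer footprints numbered 1 to 2 with a single library, and shared footprints fell to 35.4% with 50% reciprocal overlap. Except for the GC-matched flanks, which hold base composition equal, the cause was not tested. Alternatives that needed a second value per peak or a footprint value were not run, because the footprint value is 0.01 throughout and no other peak value was in the files used here.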

Other observations

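The depth test was chosen after the result was seen. A separate list of 24 genes of multiciliated cells, written before its values were looked at and sharing 0 genes with the fixed lists, had 23 open promoters, all but Dnah5. The median value of the open ones was 2.13, against 2.61 in random lists of open promoters matched on CpG ratio. The highest were Dnaic1, a dynein chain of motile cilia, at 12.7 ± 6.31 (SD, n = 2), Ccno, which acts in making many centrioles, at 9.62 ± 5.25 and Dynlrb2 at 4.84 ± 2.01. In a list of 14 genes of oviduct secretory epithelium 10 were open, with low values such as Elf3 at 1.83 ± 0.414 and Cldn3 at 1.69 ± 0.442, and none at Krt5, Muc1, Sprr1a or Ehf. These genes were chosen for mention after their values were seen.

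The first pattern weighed was the open promoters of ciliary genes in the oviduct list, such as Rsph1 and Foxj1. The oviduct list as a whole had 70% of promoters open against 60% in CpG-matched random lists (percentile 71.4). Its own share therefore does not stand out from promoter CpG content. Promoter CpG content is argued against only for the separate multiciliated list. The share of open promoters in that list, 95.8% against 70.8% in CpG-matched random lists, lay at percentile 99.98. Reads from ciliated cells of attached oviduct, or of another multiciliated epithelium, may be a source and would need such a share, but the values of the open promoters (percentile 25.1) and the distal peaks of the list (percentile 30.8) did not stand out from random lists. Secretory cells of attached oviduct stay undecided, at percentile 65.2 for the share, with low values at the open promoters (median 1.16 against 4.07 in random lists, percentile 0.17). How many of these genes ovarian cells themselves keep open is not known from these libraries, and no biological explanation was tested.

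The second pattern was the lower value of replicate 2 at strong peaks, a change of -0.88 on the log2 scale from the weakest to the strongest 10% of peaks. A depth difference is argued against by the steps of the values, whose log2 depth ratio was -0.0069 if values are CPM. A higher background in replicate 2 was predicted to give a log2 ratio of medians above 0 at the borderline peaks, and it was -0.19. Borderline peaks are those of the longer list that are not in the shorter one. They are a different set in each library, bounded by its own peak calls, and do not measure reads outside peaks. A higher background therefore stays undecided. GC content may account for part of it, since within 5 classes of GC content the smallest change was 41.7% of that over all peaks. A change of -0.36 to -0.58 stayed within each of these classes. GC content still varies inside a class, so this cannot show whether GC content is the whole of the pattern. Within classes of peak value, the ratio changed by -0.41 to -0.62 from peaks of the lowest to peaks of the highest GC content. Across shared peaks, Spearman's rho of the ratio was -0.62 with GC content and -0.53 with value. A difference between the animals stays open and untested.

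The third pattern was the low frequency of forkhead and GATA matches in distal peaks. Base composition may explain it, since in windows of equal GC content the lower ratio of the pair was 1.52, above 1. The matched set kept 73.9% of the peaks, and no biological explanation was tested.

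A hypothesis of this re-analysis was that the 2 animals differed in cell makeup or cycle stage at distal sites. Within 10 classes of peak value, the 10% of distal peaks most in favour of each library were compared, 5150 per side, of which 2141 per side could be matched on GC content. There 7 motifs passed Fisher's exact test over peaks, 6 of them by over 1.5 times. Peaks in favour of replicate 1 held more NR5A (6.26% against 3.27%), GATA (9.72% against 6.21%), forkhead (5.79% against 3.50%), SP/KLF, NRF1 and MYOD matches, and peaks in favour of replicate 2 held more CTCF matches (11.3% against 7.52%). Before matching, GATA (ratio of replicate 2 over replicate 1 of 1.12, adjusted p = 0.208, Fisher's exact test) and forkhead (ratio 1.14, adjusted p = 0.229) leaned to replicate 2 and did not pass. SOX (2.14), RUNX (1.89), STAT (1.67), LHX homeobox (3.25), NEUROD (1.23) and estrogen receptor (0.233% against 0.0388%) did pass before matching, in favour of replicate 2, and REST (0.455) in favour of replicate 1, by Fisher's exact test over peaks, and these calls were lost on matching. REST then moved further from 1, to 0.294 (adjusted p = 0.0561, Fisher's exact test). LHX homeobox stood at 2.25, SOX at 1.25, NEUROD at 1.17, RUNX at 1.15 and STAT at 1.15. Estrogen receptor matched 0.187% against 0.0934%. Matching also left fewer peaks per side, so a lost call does not show that GC content was its cause. CTCF moved from 2.58 to 1.497 and SP/KLF from 0.067 to 0.345 on matching, and the GC content of the unmatched peaks was 49.2% on the side of replicate 2 and 58.1% on that of replicate 1. With 1 library per animal and peaks chosen by their library ratio, these values do not test the hypothesis, and a difference in cell makeup or cycle stage of the animals cannot be told apart from a difference between the libraries.

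Although the mice were female, 46 peaks of replicate 1 and 44 of replicate 2 lay on chromosome Y. The highest value in each library was at 1 site, 13.3 in replicate 1 (90744621 to 90744820) and 7.81 in replicate 2 (90744601 to 90744820). The other peaks there reached at most 1.46 in replicate 1 and 1.30 in replicate 2. The cause of these peaks was not tested.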
